A study of Mus musculus with 8 samples.

How the data were processed

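Poly(A) RNA from 8 cultures of mouse muscle stem cells was sequenced by the authors as strand-specific libraries from 500 ng RNA, with 50 nt single-end reads, per the labels' protocols. STAR 2.7.11a, SAMtools 1.17 and the genome build GRCm39 are named in the submitters' processing notes. The TPM values and the FPKM values were made by the authors with StringTie 2.2.1 against their own merged annotation, per the file headers, with no correction for reads that map to several places and no option for the strand. Coverage signal per transcript was deposited in the same StringTie output. Values of paralogs, pseudogenes, antisense genes and overlapping genes are therefore uncertain, since reads may be split between them or placed without regard to strand. TPM are shares of each library, so a rise in some genes lowers the others.

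Each sample was put in its group by the label of its treatment, and the joint TPM table was read by the isolation and culture codes in its column names. The TPM of each library in the joint table matched the library's own table in all 55223 rows within a tolerance of 1e-05. Of these loci 1210 carry 2 or more gene names and 33 have damaged chromosome text. Depth was estimated as coverage times transcript length over the read length of 50 nt and lay between 48012828 and 58002740 reads per library. At that depth the spread between isolations, not read sampling, sets the precision of genes above a few TPM. Replicates were no duplicates: the chi-square of their estimated reads was 250.1, 276.1, 38.54 and 39.54 per gene, where sampling noise alone gives about 1, in vehicle_a, BMP4, vehicle_b and BMP6.

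Loci with a mean of at least 0.5 TPM over the 8 libraries were tested (16908). limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 0.5) with 4 group means and a trend in the moderated variance, so fold changes are on that scale and understate the change of low genes. Adjusted p values are Benjamini-Hochberg values, two-sided, with a threshold of 0.05. The comparisons were BMP4 against vehicle_a, BMP6 against vehicle_b, the mean of these log2 changes, their difference, and vehicle_b against vehicle_a. The test, its samples, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

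The labels give the vehicle and the stimulated library of each isolation the same isolation number, so the isolation pairs them. The deviations of paired libraries from their group means correlated at 0.707 across genes for isolations 48 and 54 and at 0.455 for isolations 75 and 77. With 2 libraries per group these deviations mirror each other, so each group pair gives 1 such value. The blocked fit, an alternative fixed beforehand, has the isolation as a fixed term, and its results stand beside the others because it changed most counts. Without the block the spread between isolations counts as noise, so limma p values tend to be too large where paired libraries deviate alike. An unadjusted p under 0.05 was then reached by 560, 213 and 405 loci for BMP4, BMP6 and either BMP, where chance gives 845.4. Not passing in that fit is therefore weak evidence against a change. Each fit takes 1 spread per gene from all 8 libraries, so the SE of a gene is the same for BMP4 and BMP6. The replicates of vehicle_a and BMP4 lay further apart (chi-square 250.1 and 276.1 per gene) than those of vehicle_b and BMP6 (38.54 and 39.54). Without the block SEs therefore tend to be too small for BMP4 and too large for BMP6. On the first principal component, with 78.04% of the variance, the libraries of the 2 experiments lay apart.

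Gene lists were 28 sets of known pathway genes and cell type markers with 581 genes, of which 10 had no locus of their own in the files. A place in a list, such as that of Bhlhe40 and Hes6 among the Notch effector genes, does not show that the pathway drives the gene in these cells. Some genes are in several lists, so calls of such lists are not independent. Dusp4, Dusp5, Fosl1 and Ier3 are both immediate early and ERK feedback genes, and Junb is both a BMP-SMAD target and an immediate early gene. The 25 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists within each comparison. With an estimated correlation, camera takes its p values from the few degrees of freedom left by the fit. Calls can thus be lost without any correlation: for BMP4 with the block, the ERK feedback genes had an estimated correlation of -0.0634. Their unadjusted camera p still went from 1.48e-08 to 0.026. With the block this setting called 0 of 25 lists in each comparison. A call lost there does not show that correlation made it. Endothelial markers, immune cell markers and erythroid genes had 1, 2 and 2 tested members and were not tested.

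Genes were named by a rule: for each BMP comparison, passing members of the BMP-SMAD and Notch effector lists, 14 fixed genes of both pathways whatever their p, the 10 largest rises and 10 largest falls that passed and lay the same way in every isolation at a mean of at least 1 TPM without Gm-number, Rik and unnamed models, and up to 3 passing members of each other list. For the difference the 3 smallest p values were named when none passed, and for the vehicles 3 in each direction. The rule was also applied to the blocked fit, which was decided after the data were seen. Of the 14 genes Hey2 lay under the filter. A result that the rule would name is not reported here.

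Alternatives were pseudocounts of 0.1 and 2, no filter, a filter of 2 TPM, FPKM, median-of-ratios and quantile scaling, voom on the estimated reads, no variance trend, each experiment alone, all 4 vehicles as 1 control, and each library left out in turn. Blocked fits with voom and without each isolation were added after the data were seen. The fits were tested on simulated data for the same 16908 genes, with 200 genes changed by BMP4 alone, 200 by BMP6 alone and 200 by both. Many more loci were thus called than in the real data, such as 276 against 4 for BMP4 without the block. That eases the adjusted threshold, so the recoveries below may be too high for the real data. Without the block 46 and 87 of 100 genes changed by 2-fold and 4-fold were recovered for BMP4, 48 and 77 for BMP6, and 74 and 93 for the mean of both. With the block these numbers were 80 and 96, 78 and 92, and 90 and 99. Unchanged genes made up 0.4 to 1.1% of the calls without and 3.1 to 5% with the block. The simulation gave each gene the same spread in both experiments, whereas the real replicates of BMP4 and BMP6 differed in theirs (chi-square 276.1 and 39.54 per gene). The recoveries and shares of unchanged genes therefore hold only for equal spread and may be off for the real data. In a simulated test of lists for BMP4, camera called the raised list and 0 of 20 unchanged lists. The simulated genes varied independently, so this test cannot show how camera treats lists whose members move together. Without the block the estimated correlation was 0.35 for the immediate early genes and 0.928 for the cholesterol synthesis genes.

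Transcript sequences of a GRCm38 annotation were used with BLAST+ 2.17.0 only to compare Gm12551 with Plin2, and all coordinates are those of the authors' files. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.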

Results

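Muscle stem cells, the satellite cells that rebuild skeletal muscle fibres, were taken from female wild-type C57BL/6J mice aged 6 to 8 weeks. They were grown for 2 days on Matrigel and then kept for 6 h without serum in the presence of 200 ng/ml BMPR-IA-Fc, a soluble receptor fragment that binds BMPs. A pulse of 1 h followed, with 100 ng/ml BMP4, 100 ng/ml BMP6 or vehicle (4 mM HCl with 0.1% BSA). The 8 poly(A) RNA-seq libraries fell into 4 groups of 2. BMP4 and its vehicle (vehicle_a) came from cell isolations 48 and 54, and BMP6 and its vehicle (vehicle_b) from isolations 75 and 77, so that each isolation gave 1 vehicle and 1 stimulated library. Transcript levels were available as TPM, which keep no depth. The coverage in the transcript files corresponded to an estimated 48012828 (BMP6 replicate 1) to 58002740 (vehicle_a replicate 1) reads per library, and 16908 gene loci with a mean of at least 0.5 TPM were tested. The question set by the series title is whether a short BMP pulse directly switches on genes of the Notch pathway.

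After 1 h of BMP4, transcripts of Smad7, Skil and Gadd45b were higher than in the vehicle libraries. The inhibitory SMAD Smad7 (merged_LIST.11882, chromosome 18, 75500600 to 75529006, GRCm39) rose from 2.69 ± 0.951 to 24.9 ± 3.45 TPM (mean ± SD, n = 2 each), a log2 change of 3.02 (SE 0.23, limma adjusted p = 0.04). The SMAD co-repressor Skil (chromosome 3, 31149207 to 31176726) rose from 13.4 ± 1.49 to 55.2 ± 8.4 TPM (log2 change 2.00, SE 0.14, adjusted p = 0.0383). The stress-response gene Gadd45b (chromosome 10, 80765907 to 80768038) rose from 24.1 ± 3.24 to 110.1 ± 4.81 TPM (log2 change 2.18, SE 0.13, adjusted p = 0.0191). All 3 were higher in both isolations given BMP4. These 3 genes and the pseudogene Gm12551, which is named here after its values were seen, made up the 4 loci that passed. Gm12551, whose transcript is 89.1% identical to Plin2 over 442 nt, was listed at 4.22 and 2.56 TPM in the vehicle_a libraries and at 0 in both BMP4 libraries.

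With the isolation as a block, 107 loci passed for BMP4, 92 higher and 15 lower, and all 4 of the loci above were among them. The Notch effector Hes1, a transcriptional repressor, stood at 12.8 ± 2 TPM in vehicle_a and 89.01 ± 42.9 TPM after BMP4, and rose by 2.67 on the log2 scale in that fit (SE 0.20, limma adjusted p = 0.0226, higher in both isolations). Without the block its SE was 0.44 and its adjusted p 0.367. Lfng, a glycosyltransferase that modifies Notch receptors, rose by 1.73 in the blocked fit (SE 0.13, adjusted p = 0.0233), and so did the dimerization inhibitor Id1 by 1.54 (SE 0.15, adjusted p = 0.0367) and Smad6 by 1.64 (SE 0.17, adjusted p = 0.042). Further rises in the blocked fit were those of the activity-regulated gene Arc (2.97, SE 0.25), the homeobox gene Dlx2 (2.76, SE 0.30), the EGF-receptor ligand Hbegf (2.36, SE 0.11), Spsb1 (2.33, SE 0.12), Bhlhe40 (2.16, SE 0.08) and Arid3a (2.12, SE 0.20). The myogenic regulator Myf5 fell in the blocked fit from 45.3 ± 10 to 19.8 ± 4.53 TPM (log2 change -1.17, SE 0.04, adjusted p = 0.00326). The growth arrest gene Gas1, the glycolytic regulator Pfkfb3, the RNase P RNA Rpph1 and the clock-associated repressor Ciart also fell in it, with log2 changes of -1.03, -1.25, -1.44 and -0.92.

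The list of BMP-SMAD target genes, fixed before the data were examined, was higher with BMP4 as a set (camera adjusted p = 3.6e-24, and adjusted p = 0.0285 with an estimated correlation). Of its 34 tested members 2 passed, 16 when adjusted over the list alone, and 29 had a positive log2 change. With the block 9 members passed (camera adjusted p = 9.62e-11, but adjusted p = 0.504 with an estimated correlation). The Notch effector genes were also higher as a set (camera adjusted p = 0.000516), a call lost with an estimated correlation (adjusted p = 0.274). None of their 10 tested members passed over all genes and 3 did when adjusted over the list alone; with the block 2 passed, Hes1 and Bhlhe40. Log2 changes of other Notch effectors, none of which passed, were 0.81 for Hey1 (SE 0.28), 0.39 for Heyl (SE 0.55) and 0.46 for Nrarp (SE 0.47). The immediate early genes (35 tested), ERK feedback and FGF target genes (16 tested), TGF-beta-activin target genes (20 tested) and osteochondrogenic genes (8 tested) had camera adjusted p values of 2.6e-12, 5.4e-06, 0.00101 and 0.00902. With an estimated correlation these 4 adjusted p values were 0.274, 0.208, 0.274 and 0.274. Adjusted over the list alone, 9, 0, 1 and 2 of their members passed. In the blocked fit 9 immediate early genes passed, among them Junb (log2 change 1.42), Gadd45b and Ier5 (0.78). The 2 ERK feedback genes that passed, Dusp5 (1.20) and Fosl1 (1.05), are also in the immediate early list and count among its 9. Sox9 (1.55) passed among the osteochondrogenic genes. Within the quiescence-associated genes of muscle stem cells 2 rose in the blocked fit, including the chemokine receptor Cxcr4 (1.39), and 2 fell, Myf5 and Gas1. Id2 (0.67, SE 0.32), Id3 (0.85, SE 0.26), Smad9 (0.53, SE 0.31), Atoh8 (0.13, SE 0.36) and Bambi (0.07, SE 0.20) did not pass in either fit, whereas Id4 passed with the block (1.25, SE 0.13).

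Without the block, the number of loci called for BMP4 rested on single libraries: it was 0 without either vehicle_b library, 1 without either BMP6 library, 16 without vehicle_a replicate 1 and 7 without vehicle_a replicate 2. It was also 0 when only the 4 libraries of isolations 48 and 54 were fitted. With the block it was 21 without isolation 75, 23 without isolation 77 and 1039 with voom on estimated reads, and with 2 replicates per group all p-values measure only the spread between these samples.

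After 1 h of BMP6, Lfng (chromosome 5, 140593075 to 140601300, GRCm39) rose from 1.22 ± 0.0299 to 8.497 ± 0.162 TPM (n = 2 each), a log2 change of 2.39 (SE 0.16, limma adjusted p = 0.0256, higher in both isolations given BMP6). It was 1 of 2 loci that passed, the other being Gm12551, listed at 7.26 and 6.05 TPM in the vehicle_b libraries and at 0 in both BMP6 libraries. With the isolation as a block 25 loci passed, 23 higher and 2 lower. Snai1, a repressor known from epithelial to mesenchymal transitions, rose in that fit from 4.21 ± 0.635 to 51.7 ± 5.79 TPM (log2 change 3.47, SE 0.25, adjusted p = 0.0411). Hes1 rose in it from 9.28 ± 4.58 to 80.03 ± 19.8 TPM (log2 change 3.10, SE 0.20, adjusted p = 0.0302). Smad7 (2.35, SE 0.10), Smad6 (2.24, SE 0.17), the forkhead gene Foxc2 (1.87, SE 0.15), Id1 (1.83, SE 0.15), Gse1 (1.71, SE 0.14), Sik1 (1.53, SE 0.06), Cxcr4 (1.49, SE 0.06) and the Hes family member Hes6 (0.50, SE 0.04) rose as well. Myf5 fell in the blocked fit from 90.2 ± 5.35 to 55.5 ± 4.5 TPM (log2 change -0.70, SE 0.04, adjusted p = 0.0192). It was the other locus beside Gm12551 that was lower.

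BMP-SMAD target genes were higher with BMP6 as a set (camera adjusted p = 7.01e-48, and adjusted p = 0.00747 with an estimated correlation). None of the 34 tested members passed over all genes, 13 did when adjusted over the list alone and 6 with the block, where the estimated correlation gave an adjusted p = 0.568. Notch effector genes had a camera adjusted p of 6.26e-12, lost with an estimated correlation (adjusted p = 0.116). Of the 10 tested, 0 passed over all genes and 4 when adjusted over the list alone, and Hes1 and Hes6 passed with the block. Hey1 (log2 change 1.25, SE 0.28), Heyl (0.31, SE 0.55) and Nrarp (0.04, SE 0.47) did not pass in either fit, and Heyl and Nrarp lay below 1 TPM in all 4 libraries of this experiment. These SEs are shared with the BMP4 comparison and also hold the spread of isolations 48 and 54. Heyl changed by 0.27 in isolation 75 and by 0.35 in isolation 77. The Notch receptors, ligands and machinery, to which Lfng belongs, had 1 of 33 members called, a median log2 change of 0.03 and a camera adjusted p of 0.0198 (adjusted p = 0.546 with an estimated correlation). Immediate early genes (camera adjusted p = 1.27e-08), TGF-beta-activin targets (0.0208) and osteochondrogenic genes (0.00146) were called as sets, and with an estimated correlation their adjusted p values were 0.546, 0.546 and 0.347. Adjusted over the list alone, 3, 0 and 2 of their members passed. The ERK feedback and FGF target genes were not called (camera adjusted p = 0.743). In the blocked fit Junb (1.00), Sik1 and Gadd45b (1.13) passed among the immediate early genes, Amotl2 (1.03) among the YAP-SRF targets and Nfkbia (1.16) among the NF-kB genes. Id3 (1.66, SE 0.26), Atoh8 (1.73, SE 0.36), Id4 (0.99, SE 0.18), Smad9 (0.95, SE 0.31), Id2 (0.63, SE 0.32) and Bambi (0.13, SE 0.20) did not pass.

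The number of loci called for BMP6 without the block was 0 without vehicle_b replicate 1, 1 without vehicle_b replicate 2 or BMP6 replicate 1, 4 without BMP6 replicate 2 or BMP4 replicate 2, and 11 without either vehicle_a library. It was 12 when only the 4 libraries of isolations 75 and 77 were fitted, and 0 with a pseudocount of 2. With the block it was 0 without isolation 75, 2 without isolation 77, 49 and 47 without isolations 48 and 54, and 73 with voom on estimated reads.

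**Figure D1:**
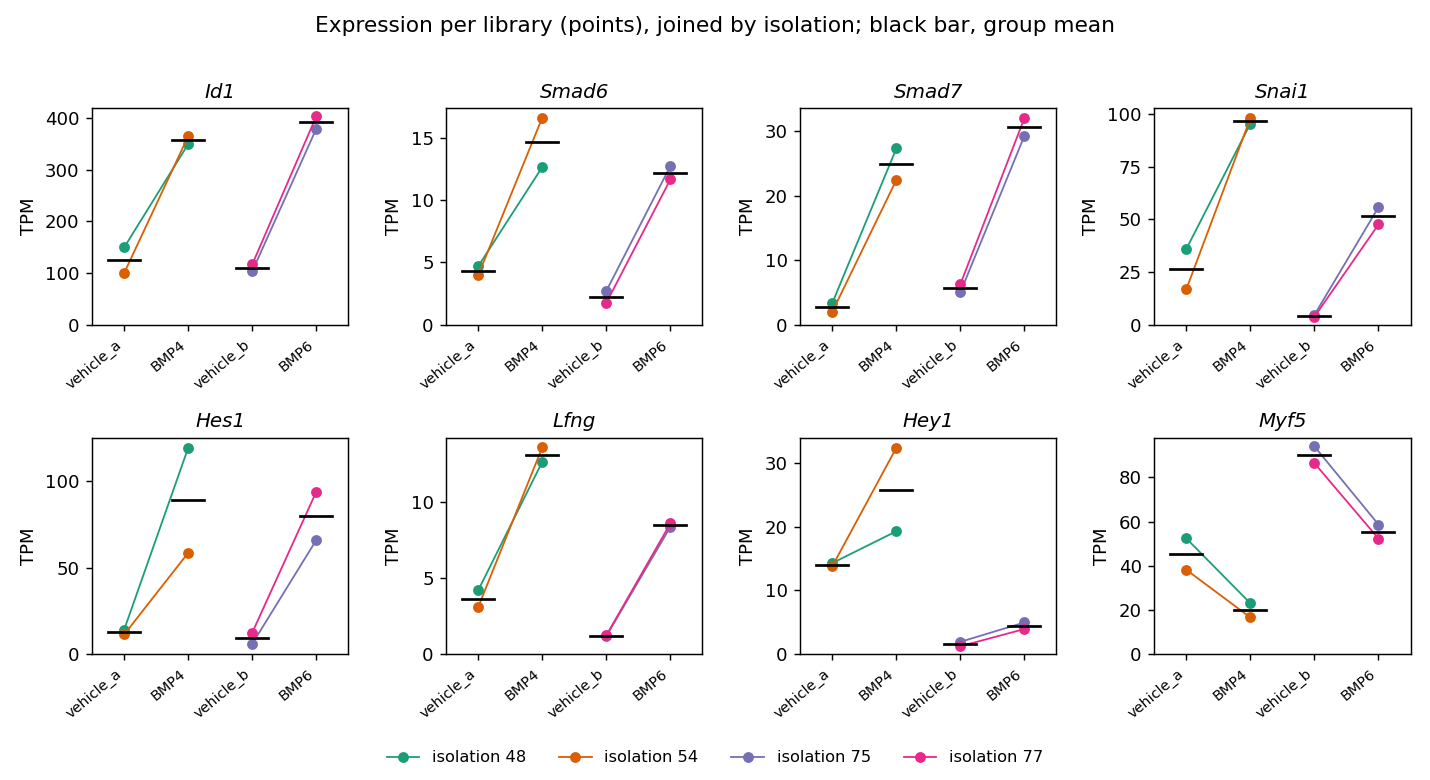
TPM of 8 genes (vertical axes, linear, from 0) in each of the 8 libraries, by group on the horizontal axis; points are libraries, coloured lines join the vehicle and the stimulated library of an isolation, and black bars are means of 2 libraries. All 4 isolations had more Id1, Smad6, Smad7, Snai1, Hes1, Lfng and Hey1 and less Myf5 after stimulation; Hey1 did not pass the test.

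Averaged over both ligands, each against its own vehicle, 12 loci passed, 11 higher and 1 lower, and each of the 11 was higher in 4 of 4 isolations. Snai1 had a mean log2 change of 2.71 (SE 0.23, limma adjusted p = 0.0228), Smad7 of 2.69 (SE 0.16, adjusted p = 0.00566), Lfng of 2.06 (SE 0.11, adjusted p = 0.00488), Smad6 of 1.94 (SE 0.15, adjusted p = 0.0212) and Id1 of 1.69 (SE 0.13, adjusted p = 0.0212). Arid3a (1.93), Skil (1.74), Gadd45b (1.66), the tight junction gene Cldn4 (1.56), Gse1 (1.38) and the AP-1 subunit Junb (1.22) were the others that rose, and Gm12551, listed at 0 in all 4 stimulated libraries, was the 1 lower locus. Hes1 had a mean log2 change of 2.89 and an adjusted p of 0.0659, and passed with the block (SE 0.14, adjusted p = 0.00653).

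With the block 114 loci passed for either BMP, 106 higher and 8 lower, and they included all 12 of the loci called without it. Among the largest rises in that fit were Hes1, Dlx2 (2.73), Snai1, Smad7, Dlx3 (2.29), the TGF-beta-inducible gene Klf10 (2.21), Lfng and Arc (1.99), and the falls included Myf5 (-0.93), the MAP kinase phosphatase Dusp10 (-0.60), Gas1 (-0.58), Ciart (-0.51), the BMP co-receptor Rgma (-0.45) and the cell cycle inhibitor Cdkn2b (-0.33). Of the 34 BMP-SMAD target genes 6 passed without the block, 21 when adjusted over the list alone and 13 with the block, including Id3 (1.25), Id4 (1.12), Smad9 (0.74), Pmepa1 (1.32) and the BMP antagonist Nog (1.61). Of the 10 tested members of the Notch effector list 0 passed without the block and 4 when adjusted over the list alone. With the block 3 passed (Hes1, Bhlhe40 and Hes6), and whether Notch drives Bhlhe40 and Hes6 here was not tested. Hey1 had a mean log2 change of 1.03 (SE 0.20) and limma adjusted p values of 0.386 without and 0.0742 with the block. The BMP-SMAD list was called as a set (camera adjusted p = 2.92e-42, and 0.00956 with an estimated correlation, but adjusted p = 0.449 with both the block and an estimated correlation), and so was the Notch effector list (camera adjusted p = 2.8e-08), but not with an estimated correlation (adjusted p = 0.195). Mixed fry, which asks for change in either direction, called the Notch effector list and 6 others of the 25 tested without the block (adjusted p = 8.21e-05), and with the block it called 20 of the 25, this list among them (adjusted p = 0.00158). Directional fry did not call it (adjusted p = 0.0986 without and 0.0561 with the block). Immediate early, ERK feedback, TGF-beta-activin and osteochondrogenic genes had camera adjusted p values of 9.6e-16, 7.16e-05, 0.000152 and 0.000213, and adjusted p values of 0.227, 0.195, 0.227 and 0.195 with an estimated correlation. Of their members 10, 0, 4 and 3 passed when adjusted over the list alone. In the blocked fit Scx (0.60) passed among the TGF-beta-activin targets, Sp7 (0.75) among the osteochondrogenic genes, Csf1 (0.87) and Nfkbia (1.08) among the NF-kB genes, Bag3 (0.28) among the heat shock genes and the pericyte marker Cspg4 (0.49). Markers of fibroblasts, pericytes, Schwann cells and adipocytes were not called by camera for the average of both ligands, with or without the block. The pericyte (adjusted p = 0.00163) and Schwann cell markers (adjusted p = 0.0391) were among the 20 lists that mixed fry called with the block. With the block the pericyte markers were also higher with BMP6 (camera adjusted p = 0.0262, adjusted p = 0.568 with an estimated correlation). The number of loci called was 0 without either vehicle_b library, 3 without BMP6 replicate 1, 20 without vehicle_a replicate 1 and 24 without vehicle_a replicate 2. With the block it was 192 without isolation 48, 15 without isolation 75, 22 without isolation 77 and 346 with voom on estimated reads.

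**Figure D2:**
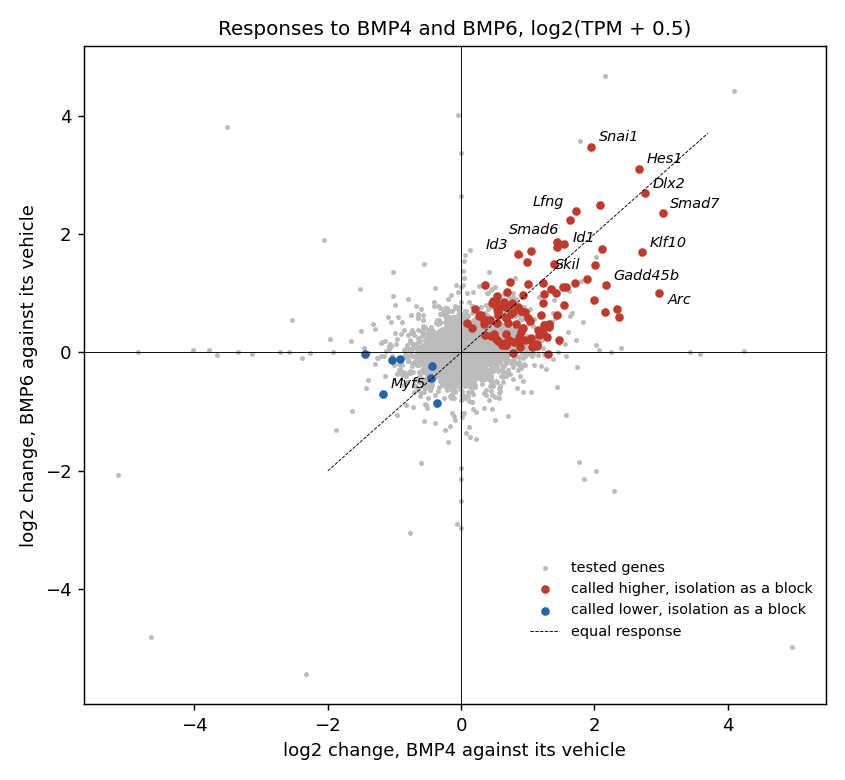
Log2 change with BMP4 (horizontal axis) against log2 change with BMP6 (vertical axis), each against its own vehicle, for the tested loci without Gm12551; coloured points are loci called for either BMP with the isolation as a block, and the dashed line marks equal responses. Smad7, Hes1 and Dlx2 lie far from 0 on both axes, while Arc (2.97 with BMP4, 1.01 with BMP6) lies nearer to the horizontal axis; differences between the ligands did not pass the test.

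The responses to the 2 ligands could be set side by side only through their own vehicles, because ligand and experiment coincide. The response to BMP6 minus that to BMP4 was -1.04 on the log2 scale for Gadd45b (SE 0.18), -1.03 for the histone demethylase homologue Jmjd1c (SE 0.19) and 0.90 for Gas1 (SE 0.18). These had the smallest unadjusted p values once Gm-number gene models were left out, and they did not pass (limma adjusted p = 1). No locus passed for the difference, with 244 at an unadjusted p under 0.05 where chance gives 845.4. Without the block the other BMP comparisons fell short of chance in the same way. Fitted to estimated reads, voom also called 0. With the block 0 passed as well, 2251 had an unadjusted p under 0.05, and the smallest adjusted p was 0.134, shared by Rnf19b (difference -0.99), Jmjd1c and Zfp36l2 (-0.96) among others. voom on estimated reads with the block called 30 loci, and the blocked limma fit called 15 without isolation 48 and 16 without isolation 54. Snai1 (1.52), Atoh8 (1.60), Sox9 (-1.42), Arc (-1.96) and Hbegf (-1.76) had larger differences that did not pass in either fit. Among the fixed lists, immediate early genes and ERK feedback and FGF target genes responded less to BMP6 than to BMP4 (camera adjusted p = 0.000176 for each, and adjusted p = 0.732 and 0.638 with an estimated correlation), with median differences of -0.34 and -0.58. Without isolation 48 the immediate early genes were not called and their median difference was 0.08 (camera adjusted p = 0.726), while the ERK feedback genes stayed lower (-0.42, adjusted p = 0.000491). The BMP-SMAD target genes had a median difference of 0.03 (camera adjusted p = 0.937) and the Notch effector genes of 0.23 (0.579). In the blocked fit 7 lists were called for the difference, and none with an estimated correlation.

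Without the block, 0 of the 3 loci higher with BMP4 and the 1 higher with BMP6 were shared, and Gm12551 was the 1 locus lower with both. In the blocked fit 18 loci were higher with both ligands, where independent lists of 92 and 23 would share 0.125, and 2 were lower with both, where lists of 15 and 2 would share 0.00177. The 2 comparisons have no library in common, although the blocked fit takes its spread from all 8. Of the 92 loci higher with BMP4, 80 also had a positive log2 change with BMP6, and all 23 of those higher with BMP6 had one with BMP4. Of the 15 loci lower with BMP4, 10 also had a negative log2 change with BMP6. Over all tested loci 49.46% had the same sign with both ligands. Across all 16908 loci, which are not independent replicates, the 2 sets of log2 changes had a Pearson correlation of 0.226 and a Spearman correlation of 0.05.

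**Figure D3:**
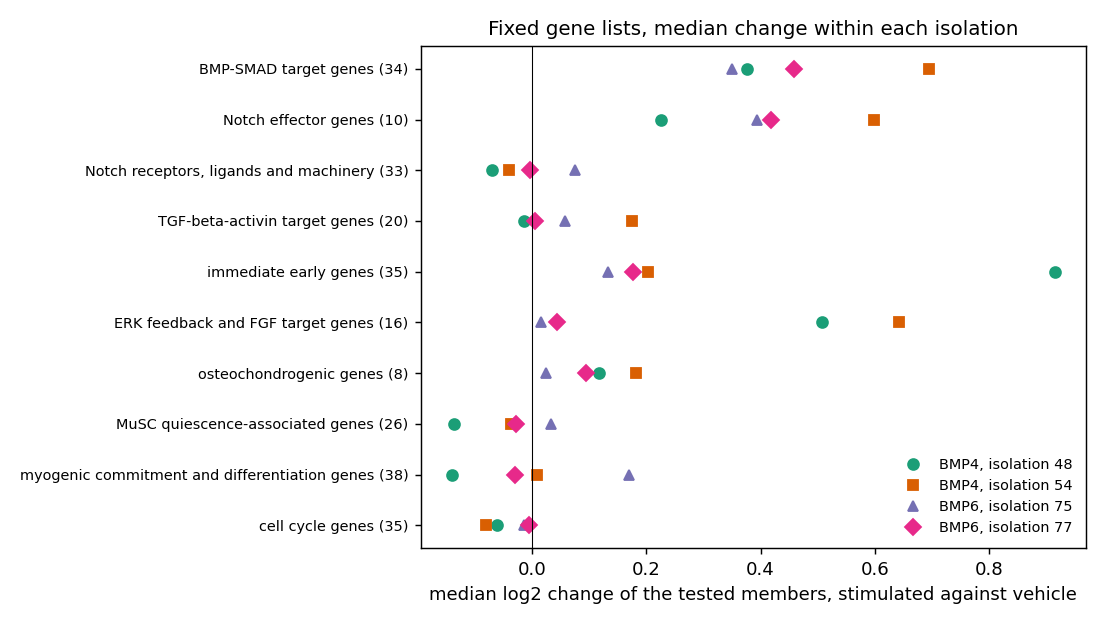
Median log2 change of the tested members of 10 fixed gene lists (number tested in brackets) in each isolation, stimulated against vehicle on the horizontal axis. The BMP-SMAD and Notch effector medians lie above 0 in all 4 isolations; the immediate early median is 0.92 in isolation 48 and 0.20, 0.13 and 0.18 in the others; the ERK feedback medians are 0.51 and 0.64 with BMP4 and 0.02 and 0.05 with BMP6.

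The vehicle libraries of the 2 experiments differed far more than either ligand did from its vehicle. Of 38 tested genes of myogenic commitment and differentiation 27 were lower in vehicle_b than in vehicle_a and 0 higher, with a median log2 difference of -3.26 (camera adjusted p = 2.48e-10, adjusted p = 0.548 with an estimated correlation). Their summed level was 11710 TPM in vehicle_a replicate 1, 33640 TPM in replicate 2, and 2580 and 3474 TPM in the vehicle_b libraries. In the same direction lay 6 of 10 Notch effector genes (camera adjusted p = 0.00429), with Heyl at 25.6 ± 14.3 TPM in vehicle_a and 0.492 ± 0.022 TPM in vehicle_b and Hey1 at 14.04 ± 0.357 and 1.6 ± 0.489 TPM. So did 5 of 7 pericyte and smooth muscle markers (0.00429) and 5 of 8 fibroblast markers (0.0197), while 7 of 16 ERK feedback genes were higher in vehicle_b and 0 lower (0.000814). With an estimated correlation the adjusted p values of these 4 lists were 0.444, 0.444, 0.444 and 0.354. Adjusted over the list alone, 36 of the myogenic genes were lower. Over all genes 4602 loci passed in limma, 1799 higher and 2803 lower in vehicle_b, and after quantile normalization 2379 were higher and 2201 lower. Kremen1 (log2 difference -2.46), Fgf21 (-2.31) and Creb3l1 (-2.97) had the smallest p values among the lower loci, and the histone gene H2bc15 (3.09), Mex3c (1.41) and H2bc4 (1.65) among the higher. Ligand, cell isolation and any batch cannot be told apart between the experiments. The count was 12 without vehicle_b replicate 1, 5 without vehicle_b replicate 2, 420 without vehicle_a replicate 2, and 2045 and 2086 without BMP6 replicates 1 and 2.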

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

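All tests of explanations in this part, including the splits of the samples, were chosen only after the results were seen.

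The immediate early genes and the ERK feedback and FGF target genes responded differently to the 2 ligands as sets (camera adjusted p = 0.000176 for each), but not with an estimated correlation (adjusted p = 0.732 and 0.638). Directional fry called neither without the block (adjusted p = 0.982 for each). With the block it called the ERK list lower in the difference (adjusted p = 0.0357) and not the immediate early list (0.356). The immediate early difference may rest on isolation 48 alone: with it left out the list no longer differed (camera adjusted p = 0.726), and its median change was 0.92 there and 0.20 in isolation 54. For the ERK list this is argued against, because with isolation 48 or 54 left out the larger adjusted p was 0.000491. A higher vehicle_b level that leaves less room to rise stays open for the ERK list, since the correlation of vehicle difference and response difference over its 16 members was -0.0142, with a 95% interval from -0.506 to 0.485. Ligand and experiment cannot be told apart, because each ligand was given in 1 experiment only.

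Among the named genes, the only ones searched for this, the values of 4 lay in opposite directions in the isolations of the 2 ligands. Over all tested loci 49.46% had the same sign with both ligands, so opposite signs were common and do not set these genes apart. The difference of the responses (BMP6 minus BMP4) was -1.43 for Dusp5, -0.36 for H2bc15, 0.74 for Nckap5l and 0.82 for Prr12 on the log2 scale. For each of these 4 genes the difference was tested with limma, with and without the block, and did not pass.

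Gm12551 was listed at 4.22, 2.56, 7.26 and 6.05 TPM in the vehicle libraries and at 0 in all 4 stimulated libraries. Exact zeros that fall without regard to treatment may account for it: 17 other tested genes were at exactly 0 in 4 libraries that follow neither treatment nor experiment. Spread evenly, such genes would put 0.515 into the 2 arrangements that follow treatment. A fall of Plin2, to which its transcript is 89.1% identical over 442 nt and 96.1% over a further 259 nt, is argued against, since Plin2 had a change of -0.0785 on the log2 scale (mean of both ligands, 2 SE on either side reaching from -0.39 to 0.23). A different placing of reads shared by Gm12551 and Plin2 needs no fall of Plin2, so it stays open and was not tested. A true loss of the transcript within 1 h stays open and was not tested.

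Hes1 rose with the block and Lfng with either BMP, while Hey1, Heyl and Nrarp did not pass. A shared rise of Hey1, Heyl and Nrarp with Hes1 stays open for BMP4, where their mean log2 change of 0.55 lay below 0.5 times that of Hes1 (1.33), but the difference of -0.78 was -1.22 in isolation 48 and -0.34 in isolation 54 (SE 0.44), within 2 SE of 0. With BMP6 their mean of 0.53 lay below 0.5 times that of Hes1 (1.55) in both isolations, by differences of -1.14 in isolation 75 and -0.89 in isolation 77 (mean -1.02, SE 0.12). So large a rise was not seen in either BMP6 isolation on this scale, but an SE from 2 isolations is itself uncertain. Heyl and Nrarp also lay below 1 TPM in those 4 libraries, where changes are understated. A shared rise with BMP6 is therefore not excluded. Whether Hes1 and Lfng respond to BMP without Notch signalling may be asked of these cells, but no biological explanation was tested, as no group had Notch blocked.

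Chance could not be excluded for the 18 genes called for either BMP with the experiment as a term. Of the 35 splits of the 8 libraries 4 gave as many, the real one included, with the highest other at 9751 for the split by experiment and the next at 922 and 76. Those 3 other splits keep both libraries of each isolation together and call more genes than the real one, which points to a structure of the samples by isolation and experiment. Among the 8 splits that part all isolations, fitted with the isolation as a block, the real one called 47 genes and the highest other 1. Only 1 of 8 was as large, and 8 splits are too few for a share under 0.05. All split fits have 1 BMP term for both ligands, so their 18 and 47 calls differ from the 12 and 114 reported for either BMP.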

How the results depend on the processing

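The voom fit with a block and the blocked fits without 1 isolation were chosen after seeing the data, and all others before. The order below is BMP4, BMP6, either BMP and the difference, with 4, 2, 12 and 0 genes as reported. The replicate block gave 107, 25, 114 and 0 genes, voom with the replicate block 1039, 73, 346 and 30, and the replicate block without isolation 48 gave 145, 49, 192 and 15, without isolation 54 97, 47, 119 and 16, without isolation 75 21, 0, 15 and 0, and without isolation 77 23, 2, 22 and 1. With no filter the counts were 8, 12, 7 and 1, and 2490 between the vehicles (4602 as reported). A pseudocount of 2 and a filter of 2 TPM left 0 and 1 genes for BMP6. FPKM and voom gave 2 each for BMP4. With only the own experiment BMP4 had 0 and BMP6 12, and with all 4 vehicles as control, which adds the difference between experiments to the spread, both had 0. Leaving out each library in turn gave 0 to 16, 0 to 11, 0 to 24 and 0 to 4 genes, and 5 to 5551 between the vehicles; a lone library was assumed to vary like the other groups. With no filter more genes are tested, and with libraries left out fewer samples are fitted; for the other changes the cause was not tested.

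Lists passing numbered 6, 6, 6 and 2 as reported. An estimated correlation gave 1, 1, 1 and 0, directional fry 2, 1, 2 and 1, mixed fry 0 for the difference, no filter 3 for BMP6, and the replicate block 7 for the difference. The BMP-SMAD list kept its call for BMP4, BMP6 and either BMP under each alternative chosen beforehand when applied alone, and the Notch effector list lost its call with an estimated correlation and with directional fry but not with mixed fry, which called 7, 5 and 7 of the 25 lists. Of 121 results for named genes, 83 passed only with the block, a number set in part by the naming rule, which was also applied to the blocked calls. None that passed as reported lost its call with the block or changed direction under any alternative run. The depth leaves genes near 0.5 TPM, such as Bambi, Nrarp and Heyl in vehicle_b, with few reads and understated changes.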

Other observations

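The lists in this part were fixed beforehand, and no test was chosen after the result was seen apart from the comparison of levels by isolation, which is given as values.

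The 4 isolations differed in their levels of myogenic genes. Summed levels of the myogenic commitment and differentiation genes were 11710 and 10710 TPM in the vehicle and BMP4 libraries of isolation 48, 33640 and 33260 TPM in isolation 54, 2580 and 2980 TPM (BMP6) in isolation 75, and 3474 and 3510 TPM in isolation 77. The list was not called by camera for BMP4, BMP6 or either BMP without the block, and with the block it was higher with BMP6 (camera adjusted p = 0.00049, adjusted p = 0.673 with an estimated correlation; median log2 change 0.06, 0 of 38 genes passing and 1 adjusted over the list alone). The list median was 0.17 in isolation 75 and -0.03 in isolation 77. Vgll2, a cofactor of muscle gene expression, fell by 0.37 on the log2 scale with BMP4 in the blocked fit.

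Between the vehicles, hypoxia and glycolysis genes were lower in vehicle_b (11 of 19, camera adjusted p = 0.0015), as were Notch receptors, ligands and machinery (10 of 33 lower and 1 higher, 0.00877), YAP-SRF target genes (9 of 18 lower and 1 higher, 0.0206) and BMP receptors, SMADs and ligands (8 of 27 lower and 1 higher, 0.029). Cell cycle genes were higher as a set (3 of 35 higher and 1 lower, 0.0439). With an estimated correlation these adjusted p values were 0.354, 0.444, 0.354, 0.794 and 0.873. The quiescence-associated genes, with 12 of 26 lower and 5 higher, were not called by camera (0.0526), but were lower by directional fry (adjusted p = 0.00108).

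With the block, the WNT target genes and cholesterol synthesis genes were called higher and the cell cycle genes lower with BMP4 as sets (camera adjusted p = 0.0337 for each), with 0 members of each passing. Only 7 of the 18 WNT target genes were tested, among them Ccnd1, also a cell cycle gene, and Myc, also an immediate early gene. Axin2, Lef1, Nkd1, Notum and Sp5 were among those under the filter of 0.5 TPM, so calls of this list do not show a WNT response. Adjusted over the list alone, 2 WNT target genes were higher, 6 cholesterol synthesis genes higher and 1 lower, and 5 cell cycle genes higher and 6 lower. With the block and an estimated correlation the adjusted p values were 0.504, 0.737 and 0.504. Without the block camera did not call the WNT target genes, but directional fry called them higher with BMP4 (adjusted p = 0.024) and either BMP (0.0179) and lower in the difference of BMP6 and BMP4 (0.0457). Interferon response genes, heat shock genes, p53 target genes, unfolded protein and amino acid stress genes, hypoxia and glycolysis genes and mitochondrially encoded protein genes were not called by camera for BMP4, BMP6 or either BMP in either fit. With the block and BMP4, directional fry called 2 lists, both higher: the p53 target genes (adjusted p = 0.0135) and the ERK feedback and FGF target genes (0.0148). Mixed fry, which asks for change in either direction, then called 20 of the 25 lists, the heat shock, p53 target, unfolded protein and hypoxia genes among them, so that its call does not set these lists apart.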
